A study of Mus musculus with 12 samples.

How the data were processed

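RNA of a mouse pulmonary artery smooth muscle cell line was measured on 6 two-colour Arraystar m6A arrays, 3 from normoxia and 3 from 8 h in 1% oxygen, with both at 37 °C and 5% CO2 in medium with 10% serum. Per the labels' protocols, total RNA was immunoprecipitated with an m6A antibody, and the bound RNA (IP) was labelled with Cy5 and the supernatant (SUP) with Cy3. No dyes were swapped.

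The deposited scanner files hold spot intensity values. Per the file headers they came from Agilent Feature Extraction 11.0.1.1 with protocol GE2_1100_Jul11, which subtracts background and applies a linear and lowess dye normalization within each array. Scaling between arrays was not done there. The authors' deposited value table holds log2 values of 37930 probes. Each column equals log2 of that channel's processed signal minus one constant, with medians between -1.93 and -0.28, and the origin of the constants is not given in the sources used here. Their direction was checked against the scanner values. Each scanner file has 33 measurement columns, of which 21 were not used.

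Each array has 62976 spots. The 1439 control spots, 15 further probes named as negative controls and spots marked non-uniform were left out, and spots of one probe were averaged on the log2 scale, leaving 60808 probes. No tested spot was saturated. The ratio was log2(IP/SUP) with each array centred on its median over the tested probes. For total RNA each channel was scaled to its 75th percentile and the channels were summed. IP and SUP alone were log2 signals minus that percentile. A probe entered the ratio test if both channels, and the total RNA test if either channel, was well above background on at least 3 of the 6 arrays. For IP and SUP that channel had to be.

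Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) with Benjamini-Hochberg adjustment at 0.05. With 3 against 3 an exact permutation test of one value cannot give a two-sided p under 0.1. The fits were tested on simulated data in which 200 probes were changed by known folds. With single-probe spreads 31.8% of 4-fold changes in the ratio were called, and with moderated spreads 89.4%. For total RNA these shares were 43.9% and 87.9%.

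Gene names came from accessions of 50 Agilent probes, each with 10 spots, matched to the GRCm38.p6 gene table without versions. The array header names an older build, so no coordinates are given. Before the data were examined, the groups, tests, gene lists, most alternatives and the rule for named genes were fixed. The rule took, for the ratio and total RNA, the 10 largest rises and 10 largest falls past the threshold, filled up by the smallest p to 5 per direction. For IP and SUP it took the 5 largest per direction, and for each list up to 4 members. It also took a set of hypoxia and m6A genes, none of which has a named probe here. Naming Kcnn2, Rab5a, Prdx2 and Anxa8 for their ratio levels, and H2-M2 and Uhrf1bp1l for completing a count, was decided after their values were seen. Gene list tests were not run.

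Alternatives were other background corrections, scalings, filters, variance models, blocks and left-out arrays. Normexp used the median signals, since no mean signal column was used. It started from signals before the dye normalization and added an offset of 50. The median processed signal per channel was 46.6 to 141, so this offset by itself shrinks log2 changes of dim probes. For spike-in scaling 1 of 22 spike-in probes was well above background in every channel. Arrays of a group correlated at 0.966 to 0.978 for total RNA and none were duplicates.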

Results

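The 6 two-colour arrays compared RNA of a mouse pulmonary artery smooth muscle cell line, the muscle cell type of the lung artery wall, after 8 h in 1% oxygen with RNA of cells kept in normal culture. Total RNA was split with an antibody against N6-methyladenosine (m6A), a methyl mark on adenosines inside RNA. The bound part (IP, Cy5) and the unbound supernatant (SUP, Cy3) of one RNA were hybridised together, giving 12 samples in 4 groups of 3. The labels call the samples of a group biological replicates. In the IP channel between 34209 and 38851 of 60808 probes were well above background per array, and in the SUP channel between 18933 and 36531. The SUP channel was dimmest in hypoxia replicate 1 and in normoxia replicate 3, which had 21951. The number of arrays, 3 per group, limits the precision of every comparison.

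The files used here do not pair most probe IDs with genes. A set of 50 Agilent probes carries accessions, 45 of these matched a gene symbol in the GRCm38.p6 gene table, and 35 named genes entered the total RNA test. Vegfa, Slc2a1, Mettl3, Fto and the other hypoxia and m6A genes chosen in advance have no named probe here and were not analysed. Of the 24 gene lists fixed in advance, 2 had a tested named gene, Gpi1 for glycolysis and E2f1 for DNA replication, and none had 2 or more, so no list was tested.

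The first comparison asked which transcripts differed in level between hypoxia and normoxia, taking the sum of both fractions as total RNA. Among the 35 named genes, 12 fell and 2 rose in hypoxia, and 21 did not pass the test. Adjusted over the list alone, the counts were again 12 and 2. The median change of the named genes was -0.39, against 0.19 over all 38785 probes tested. This excess of falls therefore does not stand for the array as a whole. Actb, the cytoskeletal beta-actin often used as a reference gene, rose from 4.46 ± 0.37 to 5.33 ± 0.02 on the log2 scale (SD, n = 3 each), a change of 0.87 (SE 0.26, limma adjusted p = 0.0161). Olfr166, an olfactory receptor gene whose probe may also bind related receptors, rose by 0.93 (SE 0.22, adjusted p = 0.00518). Scaled to the spike-in probe, neither passed, with changes of 0.25 for Actb and 0.28 for Olfr166. Neither passed with the slide as a block, where the changes were of similar size at 0.84 for Actb (adjusted p = 0.162) and 0.80 for Olfr166 (0.121). Actb also missed the threshold without normoxia replicate 2 (0.0871) and with normexp background correction, where it changed by 0.59 (0.195). Olfr166 passed with normexp at a smaller change of 0.50.

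Cep41, which encodes a centrosomal and ciliary protein, had a log2 change of -1.38 (SE 0.28, adjusted p = 0.00217). With normexp it passed at -0.52. Gsdmd, which encodes the pore-forming protein gasdermin D, went from 2.50 ± 0.14 to 1.21 ± 0.25 (SD, n = 3 each), a change of -1.28 (SE 0.23, adjusted p = 0.00106). Bambi, a decoy receptor that dampens TGF-beta signalling, changed by -1.13 (SE 0.26). Cav2, a protein of caveolae, the small pits of the cell membrane, changed by -0.99 (SE 0.26, adjusted p = 0.00873). In Cep41, Bambi and Cav2 the SUP channel was well above background on 0 of the 3 hypoxia arrays, so their totals there include SUP signal that was not above background. In the IP channel alone, which was above background on all 3, Cep41 changed by -1.40, Bambi by -1.05 and Cav2 by -0.82 (adjusted p = 0.0158). Gsta4, a glutathione transferase that detoxifies lipid peroxidation products, changed by -1.11 (SE 0.25, adjusted p = 0.00402). Rab5a, a small GTPase of early endosomes, changed by -1.09 (SE 0.24), and Tm9sf1 by -1.05 (SE 0.23). Alkbh4, a member of the AlkB dioxygenase family, changed by -1.04 (SE 0.22, adjusted p = 0.00269), and Dnajc11 by -1.02 (SE 0.28). H2-M2, whose probe may bind related histocompatibility genes, and Uhrf1bp1l were the other 2 genes that fell. With normexp, Bambi at -0.29, Gsta4 at -0.24 and Cav2 at -0.24 did not pass (adjusted p = 0.0677, 0.123 and 0.120), while Alkbh4 passed at -0.53. The normexp offset by itself shrinks changes of dim probes. The SUP channel of Gsta4 and Alkbh4 was well above background on 2 of the 3 hypoxia arrays. Scaled to the spike-in probe, the changes of Bambi, Gsta4 and Cav2 grew to -1.83, -1.72 and -1.65, yet they did not pass (0.0522, 0.0648 and 0.0762). H2-M2 and Uhrf1bp1l, at -0.86 and -0.78, likewise grew to -1.54 and -1.51 and did not pass (0.0554 and 0.0623). They also missed the threshold without normoxia replicate 1, at -0.70 each (0.0647 and 0.0623), and without hypoxia replicate 2, at -0.81 and -0.62 (0.0526 and 0.0911). Without normoxia replicate 2, Cav2 at -0.86 (0.0605) and Uhrf1bp1l at -0.69 (0.105) did not pass.

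For the DNA replication list, its 1 measured member, the cell cycle transcription factor E2f1, fell from 2.47 ± 0.24 to 1.55 ± 0.14 (SD, n = 3 each), a change of -0.92 (SE 0.23, limma adjusted p = 0.00635). It did not pass with spike-in scaling, at -1.58 (0.0584), or with the slide as a block, at -0.87 (0.102). For the glycolysis list, Gpi1, glucose-6-phosphate isomerase, stood at 7.44 ± 0.24 in normoxia and 8.37 ± 0.67 in hypoxia (SD, n = 3 each). Its difference of 0.92 (SE 0.37) did not pass at an adjusted p of 0.0572. It passed when eBayes was run without trend (0.0449), with array weights (0.0253) and without hypoxia replicate 2, at 1.29 (0.0251). With the slide as a block it grew to 1.48 and did not pass (0.0822). The difference shrank to 0.53 with quantile normalization (0.155), to 0.52 without the dimmest array of each group (0.413) and to 0.25 with spike-in scaling (0.921). Gamt, with 0.49 (SE 0.22), and Duox1, with 0.56 (SE 0.31), did not pass either, and both turned negative when scaled to the spike-in probe, at -0.17 and -0.11. Duox1 was 0.26 without hypoxia replicate 2, its highest array, and 0.06 with the slide as a block.

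**Figure D1:**
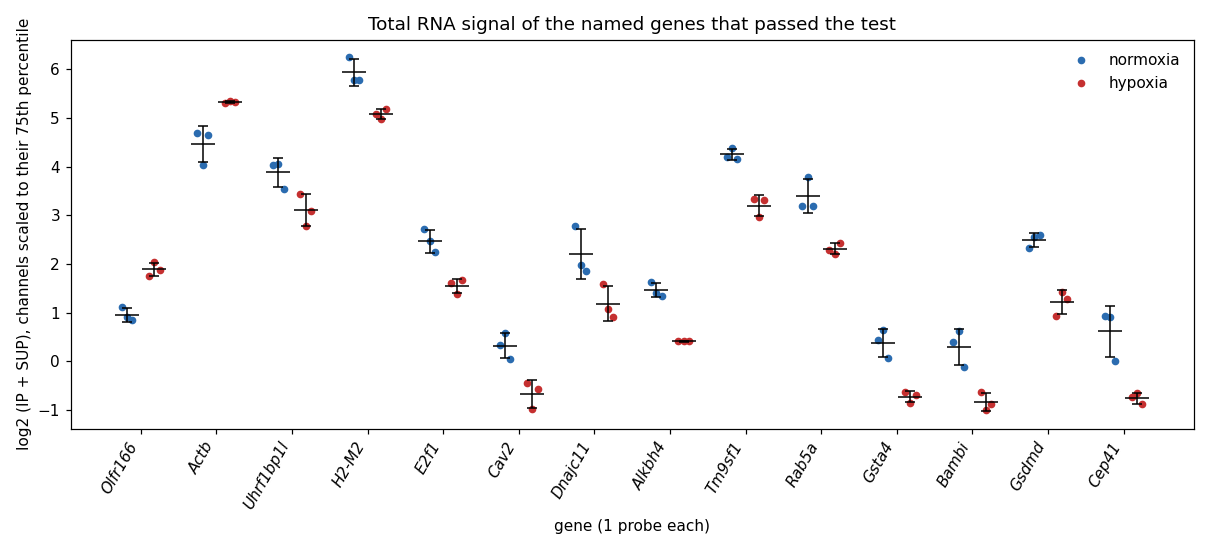
Total RNA signal, as log2 of the summed IP and SUP signals after each channel was scaled to its 75th percentile, for the 14 named genes that passed the test. Dots are single arrays, bars are means with SD over 3 arrays per group, and Actb and Olfr166 are the 2 genes higher in hypoxia.

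Across all 38785 probes tested for total RNA, 15313 passed an adjusted p of 0.05 (limma), 8275 higher and 7038 lower in hypoxia. Of these, 7748 differed at least 2-fold. The median probe changed by 0.19 on the log2 scale, by 0.05 with quantile normalization, by 0.34 with the authors' values and by -0.46 with spike-in scaling, which therefore lowers rises and deepens falls. At the main scaling and relative to the median probe, Actb changed by 0.68, Gpi1 by 0.73, E2f1 by -1.11, Gsdmd by -1.48 and Cep41 by -1.57. Among probes measured in both channels on all 6 arrays, ASMM10EP3A121297669 rose by 3.86 (SE 0.60) and ASMM10EP3A120032046 by 3.81 (SE 0.30). ASMM10EP3A103149663 changed by -2.76 (SE 0.41) and ASMM10EP3A108153469 by -2.52 (SE 0.29). The SEs are limma's moderated values. In the same order, the SDs in normoxia were 1.23, 0.23, 0.41 and 0.17 (n = 3). In hypoxia the SDs of the 4 probes were 1.49, 0.72, 1.13 and 0.67 (n = 3). These 4 were chosen after their values were seen, and the files used do not pair them with genes.

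All normoxia arrays were scanned on one day and all hypoxia arrays on another, so scan day and oxygen cannot be told apart. With the slide as a block the total RNA count was 3565, and within slide 1, which held 3 normoxia arrays and 1 hypoxia array, it was 5689. Of the 10 falls named first by size, Cep41, Gsdmd and Rab5a passed with the slide as a block, at adjusted p = 0.0399, 0.00554 and 0.0486. The 11 other named genes called for total RNA did not, though most changes were of similar size, such as -1.05 for Alkbh4 (0.0506), -1.01 for Gsta4 (0.0901) and -0.92 for Tm9sf1 (0.0901). The smallest were -0.62 for Dnajc11 and -0.44 for Uhrf1bp1l. This contrast rests on 1 hypoxia array. Without normoxia replicate 2 the count was 6867, with spike-in scaling 3128, of which 193 were higher, and with the authors' values 4296, of which 3075 were higher.

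The second comparison, the stated aim of the labels, asked whether the methylated share of transcripts differed, taking log2(IP/SUP) relative to each array's median. The dye normalization and this centring remove a shift common to most transcripts, so only differences relative to other transcripts could show. Before centring, the array medians lay between -0.08 and 0.11. Of the 27 named genes tested, none passed between the groups, also when adjusted over the list alone. Rab5a, the endosomal GTPase, had 3.01 ± 0.14 in normoxia and 3.01 ± 0.34 in hypoxia (SD, n = 3 each). Prdx2, a peroxide-reducing enzyme, had -1.59 ± 0.20 and -1.61 ± 0.47. Anxa8, a membrane-binding annexin, had 1.87 ± 0.28 and 1.70 ± 0.63. IP was always in Cy5, so such levels include any dye bias of the probe. Kcnn2, a calcium-activated potassium channel, was well above background on 6 of 6 arrays in SUP and on 0 of 6 in IP.

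The smallest unadjusted p among named genes belonged to Gsta4, with -1.13 ± 0.10 in normoxia and -0.59 ± 0.13 in hypoxia (SD, n = 3 each), a difference of 0.54 (SE 0.19, limma adjusted p = 0.565). Gsdmd differed by 0.56 (SE 0.24), Lhfp by 0.34 (SE 0.23), Hyal3 by 0.27 (SE 0.23) and E2f1 by 0.29 (SE 0.25). In the other direction were Olfr166 with -0.59 (SE 0.22) and Cpt1a, which admits fatty acids to mitochondria, with -0.54 (SE 0.29). Pex11a of peroxisomes had -0.48 (SE 0.25), Apoe, a protein of lipoprotein particles, had -0.16 (SE 0.21) and Gpi1 had -0.31 (SE 0.44). None of these 10 passed. Hyal3 was well above background in SUP on 2 normoxia arrays and 1 hypoxia array, so its ratios rest in part on signal that was not. The same holds for Gsta4, which was so on 3 normoxia arrays and 2 hypoxia arrays. With normexp most of the 10 differences shrank, to 0.24 for Gsta4, 0.27 for Gsdmd, 0.23 for Lhfp and 0.08 for E2f1. Those of Olfr166 and Cpt1a shrank to -0.27 and -0.30, and those of Hyal3 and Gpi1 turned, to -0.037 and 0.032. The normexp offset by itself shrinks differences of dim probes. Gpi1 was not dim, with mean scaled log2 signals in normoxia of 6.7 in IP and 6.1 in SUP. The offset alone therefore does not account for its turn. Normexp here also started from signals before the dye normalization. With normexp and loess within each array the differences of Hyal3 and Gpi1 were 0.051 and -0.073. Which step turned them was not tested. The E2f1 difference was 0.51 without normoxia replicate 1 and 0.12 without normoxia replicate 2. Without hypoxia replicate 2 that of Gpi1 was 0.023, and without hypoxia replicate 3 it was -0.83.

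**Figure D2:**
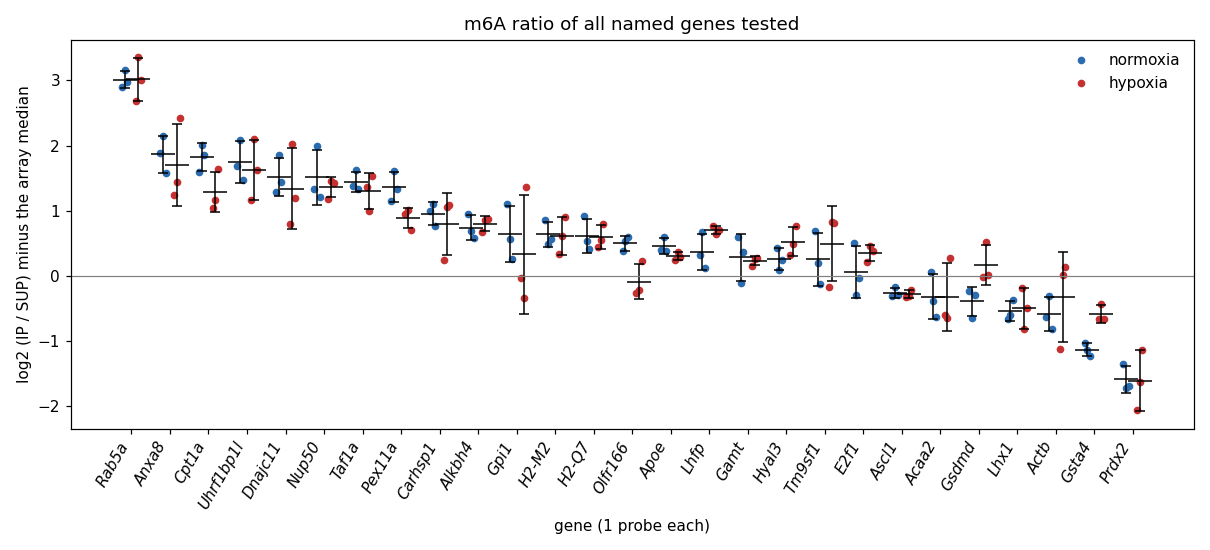
The m6A ratio, log2 of IP over SUP minus the array median, for the 27 named genes tested, ordered by their normoxia mean. Dots are single arrays and bars are means with SD over 3 arrays per group, and none of the genes passed the test between the groups, such as Rab5a with means of 3.01 in both.

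Over all 27927 probes tested for the ratio, limma called 0 at an adjusted p of 0.05, and 2072, or 7.4%, had an unadjusted p under 0.05. The median 95% confidence half-width of a probe's difference was 0.63 on the log2 scale. In simulated arrays with the moderated spread of these data, 200 of 26693 probes were changed. Of the 2-fold changes 9.0% and of the 4-fold changes 89.4% were called in the ratio. The adjusted threshold eases as more probes change, so these shares hold only for changes in few probes. Differences near 2-fold in few probes would thus mostly have been missed, and a wider change was not simulated. With the slide as a block 115 probes passed, 105 of them higher in hypoxia, and within slide 1 alone 0 passed.

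The last comparisons took each fraction by itself. In the IP fraction, Actb rose by 1.03 (SE 0.29, limma adjusted p = 0.0145) and Olfr166 by 0.69 (SE 0.23), though Olfr166 turned to -0.11 when scaled to the spike-in probe and lost its call in 8 of the other alternatives, such as the replicate block, at the same 0.69 (0.0675), and without hypoxia replicate 2, at 0.65 (0.0605). Actb did not pass with spike-in scaling, at 0.23 (0.807). Cep41 changed by -1.40 (SE 0.27), Rab5a by -1.08 (SE 0.26), Dnajc11 by -1.07 (SE 0.28), Bambi by -1.05 (SE 0.26) and Alkbh4 by -0.998 (SE 0.23), and all 5 passed. With normexp Bambi at -0.39, Alkbh4 at -0.64, Cep41 at -0.81 and Olfr166 at 0.41 were smaller but passed. Cep41 alone of these 7 passed with the slide as a block, at -1.50 (0.0295), where Rab5a at -1.13 (0.0806), Alkbh4 at -1.03 (0.0764) and Bambi at -0.94 (0.137) were of similar size and Actb at 0.57 (0.370) did not. Without normoxia replicate 2, Actb at 0.88 (0.0768), Olfr166 at 0.65 (0.102), Rab5a at -0.88 (0.0509) and Bambi at -0.84 (0.0595) did not pass. In the SUP fraction, Olfr166 rose by 1.21 (SE 0.26), and Gsdmd changed by -1.58 (SE 0.25, adjusted p = 0.00180), Gsta4 by -1.32 (SE 0.29), Tm9sf1 by -1.23 (SE 0.30), Rab5a by -1.14 (SE 0.28) and Alkbh4 by -1.12 (SE 0.26). Gsdmd alone of these 6 passed with the slide as a block (0.00508), while Olfr166 at 1.15 (0.0553), Gsta4 at -1.22 (0.0759) and Alkbh4 at -1.08 (0.0756) were of similar size, and Rab5a at -0.91 (0.157) and Tm9sf1 at -0.76 (0.213) were smaller. With spike-in scaling none passed, although the 5 falls grew, from -2.09 for Gsdmd (0.102) to -1.63 for Alkbh4 (0.233), and the rise of Olfr166 shrank to 0.71 (0.745). Without normoxia replicate 2, Gsta4 at -1.18 (0.0672), Tm9sf1 at -1.13 (0.0714), Rab5a at -0.99 (0.0898) and Alkbh4 at -1.12 (0.0581) did not pass. With normexp Gsta4 at -0.37 (0.0663) and Alkbh4 at -0.39 (0.0544) did not pass. Rab5a at -0.49, Olfr166 at 0.60 and Gsdmd at -1.05 were smaller there but passed. In both fractions the normexp offset by itself shrinks changes of dim probes. Gsta4 and Alkbh4 were well above background in SUP on 2 of the 3 hypoxia arrays, so their falls rest in part on signal that was not. Of 34 named genes tested in IP, 2 rose and 13 fell, and of 28 in SUP, 1 rose and 7 fell.

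Over all probes, 13578 of 38021 passed in IP, 7622 higher and 5956 lower in hypoxia, and 7392 of 28714 passed in SUP, 3244 higher and 4148 lower. Which direction held the majority depended on the setting in all 3 measures. For SUP it turned with the authors' values, with 843 higher and 318 lower, without a filter on dim probes, with 5438 and 4731, and without normoxia replicate 1, with 3358 and 3326. For IP it turned with spike-in scaling, with quantile normalization, with 6173 and 6809, and with the slide as a block, with 1476 and 1510. For total RNA it turned with spike-in scaling, with quantile normalization (6632 and 7811), with the slide as a block (1605 and 1960), within slide 1 (2653 and 3036), without normoxia replicate 2 (3278 and 3589) and without hypoxia replicate 2 (5021 and 5537). With the slide as a block the counts were 2986 and 2244, and within slide 1 they were 6195 and 2643. Without normoxia replicate 2 they were 4762 and 1657, and with spike-in scaling 8564, of which 359 were higher, and 265. Among 28259 probes tested in both fractions, 2649 were higher in both and 3170 lower in both, against 679 and 695 for independent lists, and 2 passed in opposite directions. The log2 changes in the fractions correlated across probes at Pearson's r = 0.89 and Spearman's rho = 0.89. Probes are not independent replicates. Both fractions come from the same RNA and cultures, were read from the same spots, were dye normalized together and share the scan days. An overlap above that of independent lists was therefore to be foreseen, and it adds no separate support.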

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

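Apart from the fits with the slide as a block, the tests in this part were chosen after the results were seen. Control spots named for 2 mouse glycolysis genes, Gapdh and Pgk1, stand outside the comparisons, and every hypoxia array lay above every normoxia array in their total RNA. The differences were 0.92 and 1.07 on the log2 scale for the probes Mouse-GAPDH_3 and Mouse-GAPDH_5, and 0.99 and 1.08 for Mouse-PGK1_3 and Mouse-PGK1_5. They are flagged here because their groups lay apart. That fixes the exact permutation p (two-sided) at 0.1, the smallest that 3 against 3 can give, so it adds no support. For Mouse-PGK1_3 the gap was narrow, with 7.084 in hypoxia replicate 2 and 7.077 in normoxia replicate 2. In SUP alone all of them lay apart. In IP alone both GAPDH probes did, while Mouse-PGK1_3 and Mouse-PGK1_5 overlapped (exact permutation p = 0.3 each).

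The first pattern weighed is the 15313 probes called for total RNA. The other 9 splits of the 6 arrays gave at most 0 calls, and 1 of 10 splits gave as many, which is too few splits for a share under 0.05; for IP, with 13578 calls, and SUP, with 7392, the highest other split also gave 0. Array brightness as the whole cause is argued against by a fit with it as a term, which gave 15228 calls, 14499 of them among the 15313 and in the same direction. A slide difference stays open as part or whole of the cause: with the slide as a block 3565 probes were called, but this rests on the single hypoxia array of slide 1. Scan day and a response to hypoxia also stay open and cannot be told apart, since 0 scan days hold both groups.

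The second pattern is the absence of calls for the m6A ratio. It says nothing about a shift common to most transcripts, which dye normalization and centring remove. All 10 splits gave 0 calls, the real one included, so the splits say nothing about chance. Limited precision is a candidate explanation for changes in few probes, since 9.0% of simulated 2-fold changes were called when 200 of 26693 probes changed. A change in many probes was not simulated. With the slide as a block, 115 probes passed, 105 of them higher in hypoxia, and 4319 had an unadjusted p under 0.05, against 2072 without the block. This contrast rests on hypoxia replicate 1, which had the dimmest SUP channel and the lowest mean ratio correlation with its own group (0.809), and within slide 1 alone 0 probes passed. It decides nothing about the slide, and ratios that differed little stay open too, and no biological explanation was tested.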

How the results depend on the processing

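The alternatives slide 1 alone, array brightness as a term, median centring and leaving out the dimmest array of each group were chosen after seeing the data. The counts of probes called in the ratio, total RNA, IP and SUP were 0, 15313, 13578 and 7392. With spike-in scaling they were 5, 3128, 8564 and 265, with 193 of the 3128 and 359 of the 8564 higher in hypoxia. This scaling rests on 1 probe, with IP signals of 11.89 to 13.15 (log2) in normoxia. With the authors' values the counts were 5, 4296, 8097 and 1161, of which 3075, 5308 and 843 of the last 3 were higher. With the slide as a block they were 115, 3565, 2986 and 2244, and within slide 1 they were 5689, 6195 and 2643 for total RNA, IP and SUP. A fold of 1.5 with an unadjusted p under 0.05 gave 1791 for the ratio and 11878 for SUP. Array weights gave 1 for the ratio and 11463 for SUP, SUP probes well above background on all 6 arrays gave 4905, where fewer probes were tested, and IP without the dimmest array of each group gave 7326. With normexp 70.1% of 17738 IP calls were higher in hypoxia, against 56.1%, and 61.9% for total RNA, against 54.0%. The majority turned for total RNA and IP with quantile normalization (45.9% and 47.6%) and the slide as a block (45.0% and 49.4%), and for SUP (43.9%) without a filter on dim probes (53.5%). Leaving out normoxia replicate 2 (47.7%) or hypoxia replicate 2 (47.6%) turned it for total RNA, and normoxia replicate 1 (50.2%) for SUP. Leaving out 1 array in turn gave 6867 to 15005 for total RNA, 4762 to 11989 for IP, 1657 to 10426 for SUP and 0 to 0 for the ratio. The lowest 3 came without normoxia replicate 2, and SUP also moved without normoxia replicate 3 (3459) and without hypoxia replicate 2 (3611). Apart from fewer arrays or probes, the cause was not tested.

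With the replicate block the counts were 0, 13218, 11661 and 6357. Correlations of same-numbered deviations in total RNA were -0.17, -0.16 and -0.23, and in the other measures they lay between -0.33 and 0.09. They show no sign of pairing, but with 3 arrays per group they cannot exclude paired cultures. Among named genes in total RNA, 295 alternative values kept direction and side of the threshold, 40 lost the call and 3, all for Gpi1, gained it. The 295 include 17 values of Gpi1, 19 of Gamt and 19 of Duox1 that kept their side by staying uncalled. The 6 falls that lost the call with spike-in scaling were larger there. Those that turned were Gamt (-0.17), Duox1 (-0.11) and the IP value of Olfr166 (-0.11) with spike-in scaling, and for the ratio Hyal3 (-0.037) and Gpi1 (0.032) with normexp. Leaving out 1 array in turn, the Gpi1 ratio ranged from -0.83 without hypoxia replicate 3 to 0.023 without hypoxia replicate 2. None of these ratios was called, and the cause was not tested. Gene list tests were not run. In SUP 31.1% of probes were well above background in hypoxia replicate 1; without it, or over probes above background on all 6 arrays, the ratio count was 0.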

Other observations

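All tests in this part were chosen after the results were seen. The probe series whose IDs carry SM1, of unknown content, had a median log2(IP/SUP) of -1.57 over 1828 tested probes, against 0.08 for the EP3A series. In each of the 6 arrays the SM1 median was low, between -1.68 and -1.33. Signal level as the whole cause is argued against, since the SM1 median was lower in each of the 10 deciles of total signal and the difference weighted over them was -1.83, against -1.64 over all probes. The difference did vary with signal, from -0.81 in the lowest decile to -3.04 in the highest. A dye bias of this series may be the source and stays open, because 0 arrays had the IP fraction in Cy3. No biological explanation was tested.

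In total RNA 613 SM1 probes were called higher and 209 lower in hypoxia, and for the EP3A series the counts were 6493 and 6280, and for the EP3B series 1144 and 530. Their median changes were 0.43, 0.14 and 0.37. The 37 tested Agilent probes went the other way, with 2 called higher, 13 lower and a median change of -0.39. Of 43 tested probes whose IDs carry SPINKEIN, 21 were called higher and 3 lower, with a median change of 0.79. The files used here do not state what the EP3B and SPINKEIN series hold.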
